A study of Homo sapiens with 23 samples.

How the data were processed

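RNA from human tissue was measured on 23 single-channel Affymetrix arrays: 10 of normal skin, 8 of squamous cell carcinoma (SCC) of the skin from immunocompetent people, and 5 of SCC from organ transplant recipients, who are immunosuppressed. Per the labels' protocols, RNA was extracted with a QIAGEN RNeasy kit, labelled with biotin and amplified by an Affymetrix double amplification. Per the submitters' processing notes, the probe level data were processed with GCRMA; its version and settings are not given in the sources used here. The deposited values are on the log2 scale, from 2.21 to 15.7, with a floor shared by all 23 arrays near which about 40.0% of the values of an array lie (38.0 to 40.4%, within 0.5 of the lowest value of the table). Differences at this floor are lower bounds. No scanner files were used here, so the quality of the arrays was read from the deposited values, and the number of arrays limits the precision of each comparison. No genome build is named in the labels, and no coordinates are given.

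Gene symbols came from the annotation of the array. It paired 10961 probe sets with 1 gene symbol, 545 with several and 1119 with none, among them 67 control probe sets. Of the single-symbol probe sets, 10949 carried a gene ID found in the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols and was used for names alone. Probe sets of the Y chromosome, XIST and TSIX (16) were left out, which left 10927. Of these, 5910 had a log2 value above 4 in at least 5 of the 23 arrays, whatever their group, and were kept. Each of the 4988 genes was represented by the kept probe set with the highest mean over all arrays; 756 genes had more than 1 kept probe set. Kept probe sets with no symbol or several symbols were tested apart from the comparisons.

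The comparisons, gene lists, tests, alternatives and rules given here were fixed before the data were examined, except where stated. The 3 comparisons were immunocompetent SCC against normal skin, transplant SCC against normal skin, and transplant SCC against immunocompetent SCC. All 23 arrays entered 1 linear model with 3 group means in limma 3.58.1 (lmFit and eBayes, R 4.3.3). P-values were two-sided and adjusted over all 4988 genes by the method of Benjamini and Hochberg, with a threshold of 0.05. The labels do not say whether the arrays of a group come from separate patients. They were treated as replicates, so the p-values measure the spread between these samples. The normal skin is labelled immunocompetent, so tumour and immune status change together between transplant SCC and normal skin.

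There were 31 gene lists with 597 distinct genes, of which 29 held at least 3 measured genes and were tested with camera in limma, two-sided, with a preset correlation between genes of 0.01 and with an adjustment over the lists of each comparison. The camera test compares a list with all other genes. It was run again with a correlation estimated from the data, and the directional and mixed tests of fry were run beside it. Members were counted with p adjusted over all genes and with p adjusted over the list alone. These counts refer to measured genes only, and many genes of the fixed lists were not measured. Programme lists covered the cornified envelope, stress keratins and alarmins, basal keratinocytes, proliferation, JAK-STAT components, STAT3 and STAT5 feedback targets, the interferon response, MHC class I and class II, calcineurin-NFAT, matrix remodelling, epithelial-mesenchymal transition, hypoxia and glycolysis, Notch, IL-17 and neutrophil chemokines, immediate-early and heat shock genes, and cytosolic ribosomal proteins. Cell type lists covered T cells, B and plasma cells, macrophages, dendritic cells, mast cells, neutrophils, fibroblasts, endothelium, muscle, melanocytes, adipocytes, sweat glands, hair follicle and sebaceous gland, and erythrocytes. A list value per array was the mean over a list's genes of the log2 value minus the gene's mean over all arrays. Group differences in it were tested by exact permutation, two-sided and adjusted over the lists of each comparison.

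Genes were named by a rule: in each comparison, among genes under the threshold, the 5 with the largest positive and the 5 with the largest negative log2 difference, and the 2 with the smallest p from each list. JAK1, JAK2, JAK3, TYK2, STAT3, IL22 and IL22RA1 were always named where measured, because the series title names ruxolitinib, an inhibitor of JAK1 and JAK2. Other list members are named where 5 or fewer members of a list passed in a direction; these were chosen after their values were seen.

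Both tumour comparisons share the normal arrays. Their overlap was set beside that of independent lists, of the 10 normal arrays split 5 and 5 by odd and even number, and of 100 simulations of unchanged tumours. In each simulation all 23 arrays were drawn as the mean of normal skin plus the residuals of whole arrays, with replacement. The normal arrays were drawn anew as well, a departure from the plan to keep them fixed, because fixed normal arrays could not carry the chance error that both comparisons share.

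Signs of RNA quality were the 3' minus 5' differences of the GAPDH and ACTB control probe sets, the mean of the non-human spike-in probe sets, the median of all probe sets and the share near the floor, compared between groups by exact permutation tests, two-sided. After the data were examined, 3 alternatives were added: leaving out each array in turn from the tests of these signs, leaving out the 3 arrays with a GAPDH difference above 2 (normal skin 6, transplant SCC 3 and transplant SCC 4), and that difference as a covariate. The alternatives fixed beforehand were no filter or a stricter filter (log2 value above 6), other choices of probe set per gene, quantile normalization, centring of each array on its median, robust and trended variances, array weights, fits of 2 groups only, the replicate number as a block, a change of at least 2-fold, a rank sum test per gene, and leaving out each array in turn. The other splits of the samples were 100 per comparison, the real one included. Figures were drawn with matplotlib 3.10.9.

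The fits were tested on simulated data, with genes shifted by log2 0.5, 1, 2 or 4. For immunocompetent SCC against normal skin, 28.0, 76.4, 93.2 and 100% of these were called, for transplant SCC against normal skin 25.2, 67.6, 95.2 and 100%, and for transplant against immunocompetent SCC 24.8, 66.8, 91.2 and 98.8%, out of 4988 genes. False calls made up 6.06, 4.64 and 5.88% of the calls in that order, 0 calls had the wrong sign, and camera called 5 of 5 shifted and 0 of 5 unshifted lists. The simulated noise was normal and independent for each gene, with no floor. These rates therefore do not carry over to lists of correlated genes or to dim genes.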

Results

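Gene expression was measured by array in normal skin (n = 10), in cutaneous SCC from immunocompetent people (n = 8) and in cutaneous SCC from organ transplant recipients (n = 5), 23 samples of human tissue in all. The series title concerns proliferation of these tumours under cyclosporine, a calcineurin inhibitor given after transplantation, and its inhibition by ruxolitinib, which blocks the kinases JAK1 and JAK2. The labels name neither drug for any sample. The filter on dim values kept 5910 probe sets, which represented 4988 genes. Values are log2 differences between group means with their standard error unless stated, and adjusted p-values are from limma.

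The first principal component held 49.6% of the variance and separated normal skin from all 13 tumours. The signs of RNA quality differed between arrays, while RNA integrity itself was not measured here. The GAPDH signal at the 3' end exceeded that at the 5' end by 1.10 ± 0.70 on the log2 scale in normal skin (SD, n = 10), by 0.63 ± 0.37 in immunocompetent SCC (SD, n = 8) and by 2.41 ± 2.51 in transplant SCC (SD, n = 5). The transplant value lay 1.78 above the immunocompetent one (exact permutation test, two-sided, p = 0.0389, adjusted over 15 tests 0.117), and ACTB gave 4.14 ± 2.60 against 2.05 ± 0.74 (SD; exact permutation p = 0.0225, adjusted 0.113), so neither passed. Without transplant SCC 4 these differences were 0.80 and 1.05, from means of 1.42 and 3.09, while without transplant SCC 1 both passed (2.38, adjusted 0.0404, and 2.62, adjusted 0.0455), as did ACTB without immunocompetent SCC 1 (adjusted 0.0473). The largest GAPDH differences were 6.34 in transplant SCC 4, 3.32 in transplant SCC 3 and 2.70 in normal skin 6, and the lowest of all arrays was 0.01 in transplant SCC 1. The spike-in mean was 8.94 in immunocompetent SCC and 9.00 in transplant SCC against 10.0 in normal skin (exact permutation p = 0.0384, adjusted 0.117, and p = 0.158, adjusted 0.200), differences of -1.07 and -1.01 that went to -0.65 and -0.59 without normal skin 6. The median of all probe sets was 3.95 in normal skin, 3.84 in immunocompetent SCC and 3.79 in transplant SCC. The fall from normal skin to transplant SCC of -0.16 (exact permutation p = 0.00200, adjusted 0.0300) and to immunocompetent SCC of -0.11 (adjusted 0.0355) passed the test. Both calls were lost without any 1 of normal skin 1, 2, 3, 4, 7 or 9, and the immunocompetent one also without immunocompetent SCC 3, 4, 7 or 8 (up to 0.0524 for transplant and 0.0663 for immunocompetent SCC). The difference of -0.05 between the tumour groups passed without immunocompetent SCC 1 (-0.06, adjusted 0.0473). No pair of arrays was near identical, with a highest correlation of 0.992.

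**Figure D1:**
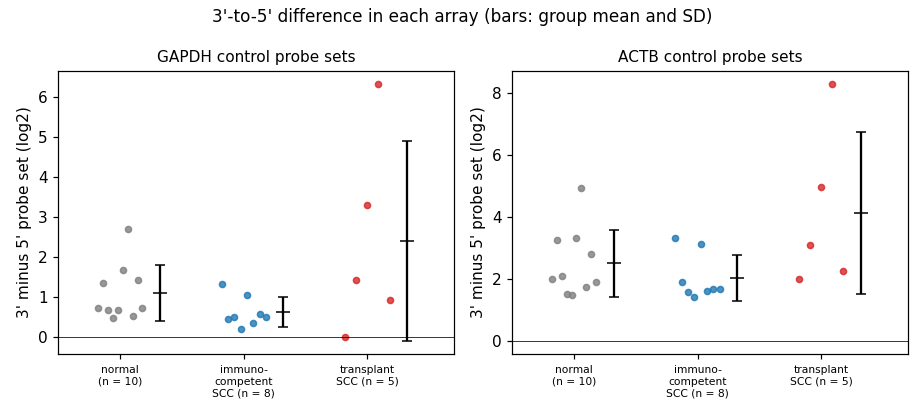
Difference between the 3' and 5' control probe sets of GAPDH and ACTB (log2 scale, vertical axis) for each of the 23 arrays by group (horizontal axis), with bars for the mean and SD. Transplant SCC 4 lies highest for GAPDH at 6.34, against 1.33 for the highest immunocompetent SCC array.

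The comparison of immunocompetent SCC (n = 8) with normal skin (n = 10) addresses how this tumour differs from healthy skin without immunosuppression. Genes of stressed and inflamed epidermis were far higher in the tumours. S100A9 and S100A8, the subunits of the inflammatory protein calprotectin, rose by 7.52 ± 0.52 (adjusted p = 1.84e-10) and 6.15 ± 0.56 (1.67e-08). S100A7 (psoriasin), PI3 (the elastase inhibitor elafin) and SERPINB3 (a protease inhibitor known as SCC antigen) rose by 6.61 ± 0.62, 6.53 ± 0.57 and 5.92 ± 0.26. Genes of sweat glands, fat and smooth muscle fell most: SCGB2A2 by -9.08 ± 0.37 (adjusted p = 3.18e-14), SCGB1D2 by -7.70 ± 0.49 and PIP by at least -7.89 ± 0.59, all secreted gland proteins, ADIPOQ (adiponectin, a hormone of fat cells) by at least -7.99 ± 0.44, and MYH11 (smooth muscle myosin) by -7.47 ± 0.51. SCGB1D2, ADIPOQ and PLIN1 (the coat protein of fat droplets) lay at the floor in the tumours and FCGR3B and IL1B in normal skin, and the group mean lay within 0.5 of the floor for PIP in the tumours (2.69) and for MMP1 (2.38) and CCL20 (2.69) in normal skin, so these differences are lower bounds. In all, 1187 genes rose and 1211 fell, 48.1% of those tested.

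Among keratinocyte programmes, all 10 measured stress keratin and alarmin genes rose, among them SERPINB3 and the cornified envelope precursor SPRR1B at 3.20 ± 0.18. The list stood above the other genes (camera adjusted p = 1.27e-10; adjusted p = 0.0536 with an estimated correlation). Of 16 genes of the cornified envelope, 11 rose and 0 fell, with the lipid transporter ABCA12 at 2.85 ± 0.25 and the envelope protein IVL (involucrin) at 2.88 ± 0.28 (camera 1.90e-04; adjusted p = 0.368 with an estimated correlation). Of 24 proliferation genes 19 rose and 0 fell, with TOP2A, a topoisomerase of dividing cells, at 1.48 ± 0.18 and the spindle factor TPX2 at 1.96 ± 0.26 (camera 1.59e-06; adjusted p = 0.305 with an estimated correlation). Of 11 basal keratinocyte genes 0 rose and 3 fell, namely the tetraspanin CD151 (-1.09), the anchoring fibril collagen COL7A1 (-0.83) and KRT15 (-1.02), a keratin of basal cells. The basal list did not pass camera (0.423). Its median was 0.00, turning to -0.10 with quantile normalization and to 0.09 with centring, and its mean was -0.30. Of 14 hypoxia and glycolysis genes 6 rose, among them the glycolytic enzymes PGK1 (0.66 ± 0.09) and HK2 (2.52 ± 0.41), and P4HA1, a collagen hydroxylase, fell by -0.53. That list passed (camera 0.0387; adjusted p = 0.305 with an estimated correlation), but not without immunocompetent SCC 1 (0.0529), 2 (0.0516) or 6 (0.0503), nor with quantile normalization (0.125) or centring (0.0567). Adjusted over the list alone, the counts of these lists were unchanged except for 2 basal genes lower.

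The JAK-STAT genes, targets of ruxolitinib and its pathway, moved both ways. Of 12 measured components 2 rose and 3 fell, and the list did not pass (camera 0.584). The transcription factor STAT5A fell by -1.50 ± 0.27, STAT5B by -0.68 ± 0.12 and the receptor subunit IL6ST by -0.78 ± 0.26, while the receptor subunits OSMR and IL2RG rose by 1.97 ± 0.40 and 0.93 ± 0.26. For STAT5A and STAT5B the other probe set did not pass. JAK1 differed by -0.24 ± 0.14 (adjusted p = 0.150), JAK2 by -0.25 ± 0.24 (0.397), TYK2 by -0.11 ± 0.14 (0.529) and STAT3 by 0.39 ± 0.24 (0.174), none past the threshold, although JAK1 passed with quantile normalization (0.0429). The other probe sets of JAK1 gave 0.87 and 0.40, and neither passed. JAK3 stayed near the floor in all arrays, with a highest value of 2.65 over 4 probe sets, and no single-symbol probe set measured IL22 or IL22RA1. Of 13 STAT3 and STAT5 feedback targets 7 rose and 1 fell. The transcription factors JUNB and MYC rose by 1.78 ± 0.22 and 2.12 ± 0.28, and CCND1 (cyclin D1) fell by -1.05 ± 0.24 (camera 0.0158; adjusted p = 0.262 with an estimated correlation). Of 13 immediate-early and heat shock genes, a list that also responds to tissue handling, 10 rose and 0 fell, among them JUNB and the mRNA decay factor ZFP36 at 1.40 ± 0.24, and 1 fell with quantile normalization (camera 0.00855; adjusted p = 0.305 with an estimated correlation). Of 9 calcineurin-NFAT genes 4 rose and 3 fell (camera 0.888). The calcineurin regulator RCAN1 rose by 1.85 ± 0.31, with EGR3, FKBP1A and NFATC1, and its relative RCAN2 fell by -4.33 ± 0.35, with the calcineurin subunits PPP3CB and PPP3CC. With p adjusted over the list alone, the counts were unchanged except for 1 immediate-early gene lower.

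Of 21 interferon response genes 11 rose and 0 fell, among them IFI27 (2.46 ± 0.37) and the GTPase GBP1 (1.86 ± 0.32), and 13 rose adjusted over the list alone (camera 0.00131; adjusted p = 0.368 with an estimated correlation). Of 10 MHC class I genes HLA-G rose (0.44 ± 0.17), and HLA-E (-0.90 ± 0.20) and HLA-F (-1.22 ± 0.41) fell. The HLA-G probe set carries the suffix f for a family of similar sequences, its call was lost with quantile normalization and without the 3 arrays of 3'-biased RNA, and the other probe set of HLA-F did not pass. Of 9 MHC class II genes 1 fell, the peptide loading chaperone HLA-DMA at -1.30 ± 0.45, lower in 6 of 8 tumours, while 3 fell with quantile normalization and 2 without the 3 arrays of 3'-biased RNA. Neither list passed (0.946 and 0.175), and the MHC class I median of 0.07 and mean of -0.14 differ in sign. Adjusted over the list alone, class I was unchanged and class II had 0 calls. In the IL-17 list of 6 genes the chemokine CCL20 (at least 3.07 ± 0.44) and the cytokines IL23A (0.99 ± 0.38) and IL1B (at least 1.55 ± 0.64) rose, and adjusted over the list alone 5 were higher and 1 lower (camera 0.140). The call of IL23A was lost without any 1 of normal skin 1, 2, 3, 5 or 9 or immunocompetent SCC 2, 5 or 6 (up to 0.0920).

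Matrix genes moved both ways. Of 17 such genes 4 rose and 4 fell (camera 0.810), with the collagenase MMP1 at 3.91 ± 0.73 or more, TNC, PLAU and PLAUR higher, and the protease MMP7 at -2.90 ± 0.52, MMP2, ITGA5 and POSTN lower. Of 10 genes of epithelial-mesenchymal transition 7 fell, among them S100A4 (-2.37 ± 0.25) and the receptor kinase AXL (-3.04 ± 0.35), both also expressed in stroma, and the epithelial cadherin CDH1 rose by 0.59 ± 0.15 (camera 0.0125; adjusted p = 0.368 with an estimated correlation), while 2 of the list rose under either scaling. Of 8 Notch genes the protease ADAM17 rose (0.79 ± 0.14), and the ligand JAG2 (-1.28 ± 0.23), RBPJ, HES1 and NOTCH3 fell (camera 0.231). Of 25 cytosolic ribosomal protein genes 15 fell and 0 rose, with RPL13 at -0.59 ± 0.10 and RPS9 at -0.69 ± 0.12 (camera 7.48e-04; adjusted p = 0.368 with an estimated correlation), and 13 fell with quantile normalization and 9 with centring. With p adjusted over the list alone, the counts were unchanged except for 8 transition genes lower.

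The lists of fat, sweat gland, muscle, fibroblast, vessel and mast cell markers were lower in the tumours beside these changes. All 8 adipocyte genes fell (ADIPOQ, PLIN1 at -6.62 ± 0.46; camera 2.46e-06; adjusted p = 0.262 with an estimated correlation), as did 9 of 11 sweat gland genes (SCGB2A2, the ductal keratin KRT19 at -5.14 ± 0.32; 1.89e-07; adjusted p = 0.0536 with an estimated correlation) and 9 of 11 muscle genes (MYH11, ACTG2 at -6.95 ± 0.55; 3.14e-06; adjusted p = 0.262 with an estimated correlation). Of 15 fibroblast genes 8 fell (the protease CFD at -6.07 ± 0.42, FBLN1 at -4.21 ± 0.35; 3.31e-04; adjusted p = 0.368 with an estimated correlation), but the other probe set of the matrix gene FBLN1 gave 0.04. Of 9 endothelial genes 8 fell, with CLDN5 at -2.43 ± 0.38 and PECAM1 at -2.56 ± 0.49, and the VEGF receptor FLT1 rose by 1.87 (0.0161; adjusted p = 0.368 with an estimated correlation). Of 3 mast cell genes GATA2 (-1.96 ± 0.31) and CTSG (-2.85 ± 0.48) fell (0.0490; adjusted p = 0.368 with an estimated correlation). The mast cell call was lost without normal skin 3, 5, 6, 8, 9 or 10, immunocompetent SCC 1, 4, 7 or 8 or transplant SCC 1, 3, 4 or 5, each left out alone (up to 0.0718), without the 3 arrays of 3'-biased RNA (0.0656), with the GAPDH covariate (0.0580) and with the mean of all probe sets (0.0534). Adjusted over the list alone, the counts were unchanged except for 10 sweat gland genes lower.

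The remaining cell type lists did not pass camera. Of 5 T cell genes the receptor gene TRBC1 rose by 0.77 ± 0.28, a call lost without immunocompetent SCC 2, 5 or 6 (up to 0.0677) and adjusted over the list alone (camera 0.423). Of 13 macrophage genes FCGR3A rose (2.56 ± 0.63) and MRC1 (-1.42 ± 0.38), CD14 and APOE fell (0.693). Of 8 dendritic cell genes LAMP3 (1.54 ± 0.32), CD83 (0.57 ± 0.18) and CCL22 rose and CD1C fell (0.693), with 2 lower adjusted over the list alone. Of 4 neutrophil genes CXCR2 (1.52 ± 0.32) and FCGR3B (at least 1.63 ± 0.46) rose (0.135). Of 6 melanocyte genes MITF (-1.72 ± 0.45) and SOX10 (-0.38 ± 0.13) fell (0.231), SOX10 not with quantile normalization (0.183), and 1 of these genes fell with centring. Of 14 hair follicle and sebaceous gland genes ACO1 (-1.92 ± 0.38), FASN (-1.33 ± 0.39) and KRT31 fell (0.140), and the list passed without the filter on dim probes (0.0443). B and plasma cells (JCHAIN 1.11, XBP1 0.12) and erythrocytes (HBB -0.31) had too few genes for a list test and 0 calls. With p adjusted over the list alone, the counts not given here were unchanged. Of 29 lists 15 passed camera, 7 higher and 8 lower, and 0 did so with an estimated correlation. The list values per array, which are not set against other genes, also passed for lists that camera left out (exact permutation test). They were higher for IL-17 (adjusted p = 1.66e-04) and neutrophils (0.00203). They were lower for Notch (4.26e-04), calcineurin-NFAT (0.00183) and basal genes (0.00815). The calcineurin-NFAT difference of -0.27 took its sign from RCAN2 alone, at -4.33. With a median over its genes the difference was 0.0257 (exact permutation test, adjusted p = 0.783). Of 61 named genes that passed, 56 lay on the called side of the mean of normal skin in all 8 tumours, the others in at least 6.

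**Figure D2:**
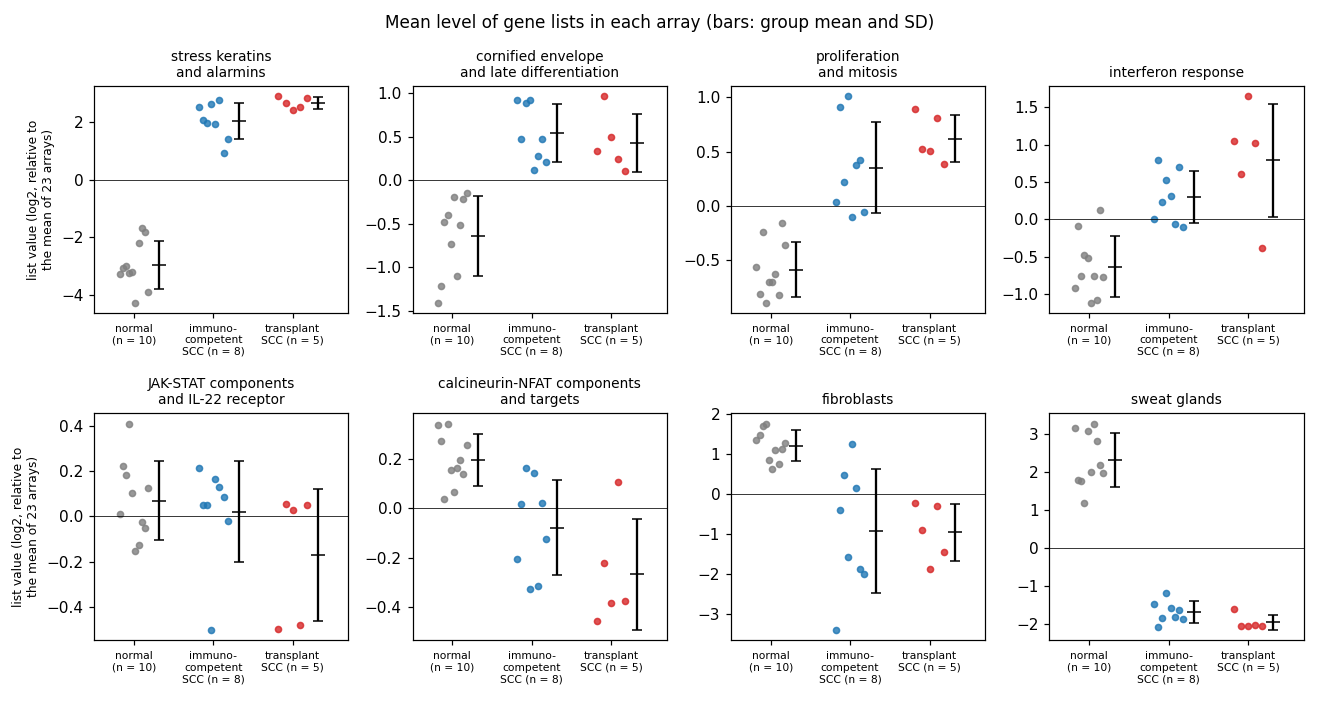
Mean over the genes of 8 lists of the log2 value minus the gene's mean over all arrays (vertical axis, log2 scale), 1 point per array by group (horizontal axis), with bars for the mean and SD. In both tumour groups the stress keratin and proliferation lists lie above normal skin and the sweat gland list below it.

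Transplant SCC (n = 5) was compared with the same normal skin (n = 10) to see how tumours arising under immunosuppression differ from healthy skin, a contrast in which tumour and immune status change together. Of the 5 genes with the largest rises and the 5 with the largest falls, 8 were those of the first comparison. S100A9 rose by 7.53 ± 0.60 (adjusted p = 2.13e-09), PI3 by 7.33 ± 0.66, S100A7 by 6.45 ± 0.72, S100A8 by 6.24 ± 0.65, and AKR1B10, an aldo-keto reductase, by 6.81 ± 0.47 (2.00e-10). SCGB2A2 fell by -9.38 ± 0.43 (3.71e-13), PIP by -7.87 ± 0.69, SCGB1D2 and ADIPOQ by at least -7.69 ± 0.57 and -7.98 ± 0.51, and FABP4, a fatty acid carrier of fat cells, by -7.37 ± 0.96. In all, 1116 genes rose and 1220 fell, 46.8% of those tested. Without the 3 arrays of 3'-biased RNA 886 rose and 1090 fell. Scaling moved the median of all genes by 0.12 (quantile normalization) or 0.11 (centring) in this comparison.

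All 10 stress keratin and alarmin genes rose again, among them SERPINB3 (6.11 ± 0.30) and SPRR1B (3.59 ± 0.21), a list that also passed with an estimated correlation (camera 1.05e-11; adjusted p = 0.0408 with an estimated correlation). Of 16 cornified envelope genes 8 rose, with IVL at 3.44 ± 0.33 and the crosslinking enzyme TGM1 at 3.13 ± 0.34, and the suprabasal keratin KRT2 fell by -0.93, a call lost under either scaling (0.00128; adjusted p = 0.464 with an estimated correlation). Without the 3 arrays of 3'-biased RNA 6 of them rose. Of 24 proliferation genes 19 rose and 0 fell, with CCNB1 (cyclin B1) at 2.36 ± 0.29 and the spindle checkpoint kinase TTK, whose normal mean of 2.54 lay near the floor, at 2.11 ± 0.27 or more (4.00e-08; adjusted p = 0.263 with an estimated correlation), and 21 rose and 1 fell adjusted over the list alone. Of 11 basal genes KRT14 (0.47 ± 0.13) and KRT5 rose, and COL7A1 (-1.86 ± 0.29), KRT15, ITGB4 and ITGB1 fell (0.522). The call of KRT14 was lost with quantile normalization (0.194), and 1 basal gene rose and 2 fell without the 3 arrays. Of 14 hypoxia and glycolysis genes 9 rose and 0 fell, with the glucose transporter SLC2A1 at 1.44 ± 0.21 and the glycolytic enzyme TPI1 at 0.67 ± 0.13 (0.00308; adjusted p = 0.190 with an estimated correlation). Adjusted over the list alone, the other counts were unchanged.

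Of 12 JAK-STAT components 0 rose and 4 fell, namely STAT5A (-1.49 ± 0.31), IL6ST (-1.20 ± 0.30), TYK2 (-0.50 ± 0.17) and IL6R (camera 0.354), but 2 fell with quantile normalization, and 1 rose with centring or without the 3 arrays. The call of the kinase TYK2 (adjusted p = 0.0162) was lost without transplant SCC 4 (0.0913), without the 3 arrays of 3'-biased RNA (0.0530), with the GAPDH covariate (0.0869) and with quantile normalization (0.0731), and the other probe set of STAT5A did not pass. JAK1 differed by -0.31 ± 0.16 (adjusted p = 0.116), a difference that passed with the covariate at -0.49 (0.00971), without the 3 arrays at -0.51 (0.0341) and without transplant SCC 2 at -0.41 (0.0458). The other probe sets of JAK1 gave 0.33 and 0.71, and neither passed. JAK2 differed by -0.51 ± 0.28 (0.134), passing without normal skin 6 at -0.62 (0.0490), and STAT3 by 0.56 ± 0.27 (0.0940). Of 13 feedback targets 7 rose, with the kinase PIM1 at 1.51 ± 0.27, and CCND1 (-1.69 ± 0.28) and BCL6 fell (0.216). Of 13 immediate-early and heat shock genes 7 rose and 0 fell, with ZFP36 at 2.00 ± 0.27 and JUN at 0.79 ± 0.17 (0.0181; adjusted p = 0.414 with an estimated correlation), a list call lost with quantile normalization (0.0567). Of 9 calcineurin-NFAT genes RCAN1, FKBP1A and NFATC1 rose and RCAN2 (-4.10 ± 0.41), PPP3CC (-1.27 ± 0.25), PPP3CB and NFATC3 fell (0.518). The median of that list, -0.10, turned to 0.12 with quantile normalization and to 0.02 with centring, and 1 of its genes rose without the 3 arrays. With p adjusted over the list alone, these counts were unchanged.

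Of 21 interferon response genes 14 rose and 0 fell, also adjusted over the list alone, with the oligoadenylate synthetase relative OASL at 4.23 ± 0.59 or more and MX1, an antiviral GTPase, at 2.57 ± 0.37 (4.30e-05; adjusted p = 0.414 with an estimated correlation). Without the 3 arrays of 3'-biased RNA 8 rose. HLA-E (-2.17 ± 0.23) and HLA-G (-0.50 ± 0.19) fell among 10 MHC class I genes (0.377), and HLA-DMA (-1.34 ± 0.51) and HLA-DPB1 (-1.03 ± 0.41) among 9 of class II (0.512). Adjusted over the list alone, 1 class I gene and 0 class II genes were lower. With quantile normalization 2 class I genes rose and 2 fell, with centring 1 rose and 1 fell, and of class II 1 fell with centring and 3 without the 3 arrays. The calls of HLA-G, HLA-DMA and HLA-DPB1 (adjusted p = 0.0359, 0.0362 and 0.0417) were lost without any 1 of 7, 9 and 8 arrays: transplant SCC 1, 2 or 4 for all of them, transplant SCC 5 for HLA-G and HLA-DMA, and normal skin 5, 8 or 10 for HLA-G, 1, 2, 3, 9 or 10 for HLA-DMA and 3, 4, 8, 9 or 10 for HLA-DPB1 (up to 0.106, 0.154 and 0.199). In the IL-17 list CCL20 (at least 2.08 ± 0.50) and IL23A (1.40 ± 0.44) rose, also adjusted over the list alone (0.175), the call of IL23A being lost without transplant SCC 3 (0.0628) and without the 3 arrays of 3'-biased RNA (0.106).

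Of 17 matrix genes 7 rose, with MMP1 at 5.63 ± 0.84 or more and the protease PLAU (urokinase) at 2.30 ± 0.41, and MMP7, MMP2 and POSTN fell (camera 0.358). Of 10 transition genes 6 fell, with AXL at -3.33 ± 0.41 and S100A4 at -2.13 ± 0.29, and CDH1 rose by 0.59, a call lost without the 3 arrays (0.0199; adjusted p = 0.475 with an estimated correlation), a list call lost without transplant SCC 3 (0.0523). Of 8 Notch genes ADAM17 (0.81 ± 0.16) rose and JAG2 (-1.77 ± 0.26), RBPJ, HES1 and MAML1 fell (0.191). Of the other 2 probe sets of ADAM17, 0 passed, and 1 gave -0.04. Of 25 ribosomal protein genes 16 fell and 0 rose, with RPS6 at -0.73 ± 0.12 and RPLP1 at -0.58 ± 0.10, whose other probe set gave 0.12 (3.16e-04; adjusted p = 0.455 with an estimated correlation), and 13 fell with quantile normalization or without the 3 arrays and 9 with centring. With p adjusted over the list alone 17 ribosomal genes fell, and the other counts were unchanged.

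Markers of fat, sweat glands, muscle, fibroblasts and vessels were again lower as lists. Of 8 adipocyte genes 8 fell (1.26e-05; adjusted p = 0.263 with an estimated correlation), of 11 muscle genes 9 (MYH11 at -7.35 ± 0.58, ACTG2 at -6.96 ± 0.64; 3.59e-05; adjusted p = 0.263 with an estimated correlation) and of 15 fibroblast genes 7 (CFD at -6.32 ± 0.49, FBLN1 at -5.18 ± 0.41; 0.00128; adjusted p = 0.475 with an estimated correlation). Of 11 sweat gland genes 10 fell, with KRT19 at -5.37 ± 0.37, a list that also passed with an estimated correlation (4.00e-08; adjusted p = 0.0408 with an estimated correlation). Of 9 endothelial genes 7 fell, with VWF at -2.69 ± 0.36 and CLDN5 at -2.69 ± 0.44, and FLT1 rose (0.0339; adjusted p = 0.475 with an estimated correlation). The endothelial call was lost without transplant SCC 3 (0.0692), without the 3 arrays of 3'-biased RNA (0.0629) and with the stricter filter (0.0783), and 4 of its genes fell with quantile normalization and 5 with centring. Of the other cell types, LAMP3 (1.96 ± 0.37) and CD83 (0.90 ± 0.21) of dendritic cells and CXCR2 (1.37 ± 0.37) of neutrophils rose. APOE (-2.84 ± 0.77), CD14 (-0.96 ± 0.34) and MRC1 of macrophages, GATA2 (-1.64 ± 0.36) and CTSG (-2.44 ± 0.55) of mast cells, MITF (-2.08 ± 0.52) of melanocytes, and FASN (-1.61 ± 0.45), LGR5 (at least -2.42 ± 0.81), ACO1 and ELOVL5 of the hair follicle and sebaceous gland fell. None of these 6 lists passed camera (0.359, 0.377, 0.495, 0.116, 0.198 and 0.112 in the order given), nor did T cells (0.359). T cells had 0 calls (TRBC1 0.36), as had B and plasma cells (XBP1 -0.30) and erythrocytes (HBB 0.44). The hair follicle and sebaceous gland list passed without transplant SCC 5 (0.0329), with quantile normalization (0.0460), with centring (0.0497) and with no filter (0.0264), and the mast cell list with no filter (0.0243). CD14 lost its call without transplant SCC 1, 2 or 4 (up to 0.0929), and CD14, FASN and LGR5 without the 3 arrays of 3'-biased RNA (0.172, 0.102 and 0.0842), when 0 hair follicle and sebaceous gland, 6 adipocyte and 5 endothelial genes fell. With quantile normalization 2 macrophage genes rose and 1 fell, and with centring 2 rose and 2 fell. Adjusted over the list alone, 1 macrophage gene fell, and the other counts were unchanged. Of 29 lists 13 passed camera, 6 higher and 7 lower, and 2 did so with an estimated correlation. The list values per array also passed for other lists (exact permutation test). IL-17 and feedback targets were higher (both adjusted p = 6.90e-04), as was matrix (0.0111). Notch and mast cells (both 6.90e-04), calcineurin-NFAT (0.00170), basal genes (0.0107), melanocytes (0.0138) and hair follicle and sebaceous gland (0.0373) were lower. Among the 9 calcineurin-NFAT genes, with a mean of -0.46, RCAN2 at -4.10 made up nearly all of the net fall.

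Changes from normal skin were shared widely between the tumour groups. Of the genes that rose, 763 did so in both comparisons, 64.3% of the immunocompetent calls and 68.4% of the transplant calls, and of those that fell 853 did, 70.4 and 69.9%. Independent lists would share 265.6 and 296.2. Simulated unchanged tumours shared 0 with a mean of 0 and 0.07 calls in the 2 comparisons, too few for that count to measure sharing. With the normal arrays split between the comparisons, 518 and 581 genes were shared in 1 split and 481 and 584 in the other. Across genes, which are not independent replicates, the log2 differences correlated with r = 0.90 (simulated mean 0.35, highest 0.84; 0.88 and 0.84 in the splits), with a covariance of 1.05 against a simulated 0.0283 and 1.04 and 1.02 in the splits. Only 8 genes passed in opposite directions in both comparisons with normal skin, against 561.3 for independent lists and 2 and 3 in the splits. HLA-G, LARP1, PSMD3, RXYLT1 and TLE4 were higher in immunocompetent and lower in transplant SCC than in normal skin, and ABCC10, ALDH7A1 and TLK2 the reverse.

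**Figure D3:**
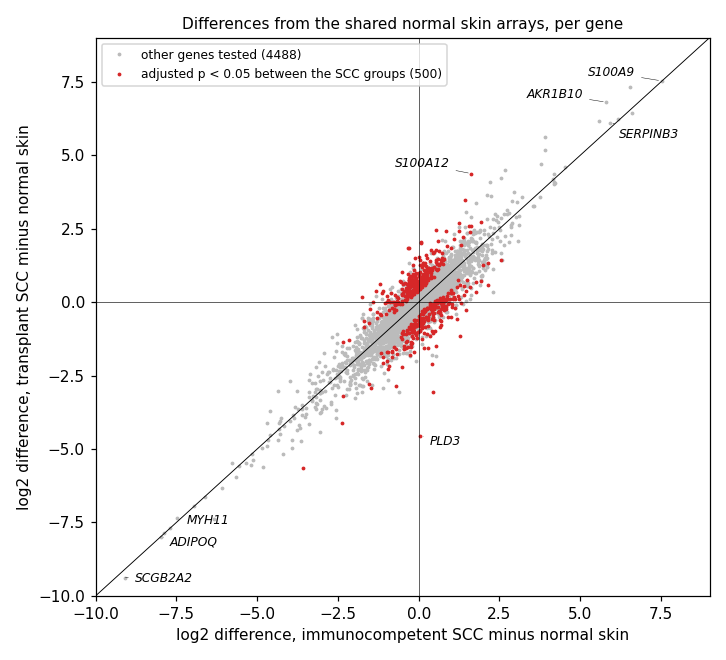
Log2 difference from normal skin in transplant SCC (vertical axis) against that in immunocompetent SCC (horizontal axis), 1 point per gene for 4988 genes, with the 500 genes that differed between the tumour groups in red. Most genes lie along the diagonal, with r = 0.90 across genes.

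The direct comparison of transplant SCC (n = 5) with immunocompetent SCC (n = 8) asks what distinguishes tumours of immunosuppressed people, and it is also the test of whether the changes from normal skin differ. Here 267 genes were higher and 233 lower in transplant SCC, 10.0% of those tested. The alarmin S100A12, a calcium-binding protein of inflamed epidermis and myeloid cells, was higher by 2.75 ± 0.53 (adjusted p = 0.00278) and the nucleoside enzyme UPP1 by 2.05 ± 0.65 (0.0480). The drug-metabolising enzymes CYP2A6 (2.18 ± 0.17, 1.38e-08) and CYP2A13 (2.15 ± 0.29, 1.27e-04) and the vesicle protein SCAMP5 (1.98 ± 0.13, 1.02e-09) were higher by probe sets of suffix r, for which the usual rules of probe selection were relaxed. The lysosomal protein PLD3 was lower by -4.60 ± 0.59 (7.40e-05), the translation factor EIF2S3 by -3.51 ± 0.97 (0.0247), the kinase RPS6KB2 by -2.52 ± 0.67 (0.0205), the pseudogene GUSBP11 by -2.42 ± 0.75 (0.0406) and the receptor EPHB3 by -2.17 ± 0.68 (0.0432). Of the 5 transplant arrays, 3 and 4 also had strongly 3'-biased RNA, and the groups did not differ past the threshold in the GAPDH sign (adjusted p = 0.117). Without the 3 arrays of 3'-biased RNA 97 genes were higher and 92 lower, of which 174 were among the 500. Without transplant SCC 4 alone 333 genes passed, 171 of them higher. The number lower, 233, was 146 without transplant SCC 1, 147 without transplant SCC 3, and 149 and 148 without immunocompetent SCC 7 and 8.

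No list separated the tumour groups (camera, lowest adjusted p = 0.207 for proliferation and for the interferon response, 1313 single genes under an unadjusted p of 0.05), and fry called 0 lists in its directional and 1 in its mixed test, the ribosomal proteins (0.00270). The list values per array did not pass for any list either (exact permutation test, lowest adjusted p = 0.661). Of 24 proliferation genes KIF2C, a mitotic kinesin (0.82 ± 0.21), and CCNA2 (cyclin A2, 1.20 ± 0.35) were higher, 3 adjusted over the list alone. The proliferation list passed without immunocompetent SCC 2 (0.0311) or 4 (0.0203). Of 21 interferon genes 0 passed, also adjusted over the list alone, and 1 was higher under either scaling, with the list under the threshold without transplant SCC 5 (3.77e-04). The hypoxia genes SLC2A1 (0.91 ± 0.22), NDRG1 (0.62 ± 0.19) and BNIP3 (1.23) were higher, and 4 higher and 1 lower adjusted over the list alone. The invasion protease CTSL (1.12 ± 0.32) and the basal keratin KRT14 (0.46 ± 0.13) were higher, and COL7A1 (-1.03 ± 0.30), the desquamation protease KLK7 (-0.82 ± 0.26), JUNB (-1.10 ± 0.27), the chaperone HSP90AA1 (-0.54 ± 0.14), HLA-E (-1.26 ± 0.24) and HLA-G (-0.95 ± 0.20) were lower. With p adjusted over the list alone, 3 MHC class I genes and 3 feedback targets were lower and 0 cornified envelope genes, and the matrix, stress keratin, basal and immediate-early counts were unchanged. Of 25 ribosomal proteins RPL38 (0.44 ± 0.12) was higher and RPS6 (-0.49 ± 0.13), RPL18 and RPL9 were lower, 1 and 5 adjusted over the list alone. Without the 3 arrays of 3'-biased RNA 1 hypoxia gene was higher, and the cornified envelope, basal, proliferation, feedback, matrix, immediate-early and ribosomal lists had 0 calls.

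Of 12 JAK-STAT components 0 passed between the tumour groups, also adjusted over the list alone, and 1 was higher under either scaling. This count rests on 1 probe set per gene. Another probe set of STAT5B was higher in all 5 transplant arrays than in all 18 others (mean 6.11 against 4.67). JAK1 differed by -0.06 ± 0.16 (adjusted p = 0.851), turning to 0.08 without transplant SCC 1, to 0.06 without transplant SCC 5 and to 0.31 with another probe set, JAK2 by -0.26 ± 0.29 (0.621), TYK2 by -0.39 ± 0.17 (0.152) and STAT3 by 0.17 ± 0.28 (0.761), or -0.38 with another probe set. The calcineurin-NFAT genes, MHC class II, Notch, IL-17 and transition lists and every cell type list had 0 calls, also adjusted over the list alone. Many genes of these lists were not measured. Only 5 of 31 T cell, 2 of 18 B and plasma cell, 3 of 10 mast cell and 4 of 11 neutrophil genes were. For IL-17 it was 6 of 18 and for calcineurin-NFAT 9 of 25. The absence of calls says nothing of the genes not measured. Of the 24 named genes that passed, 21 lay on the called side of the immunocompetent mean in all 5 transplant arrays and EPHB3, JUNB and SLC2A1 in 4.

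Of these 24 genes, S100A12, CYP2A6, CYP2A13, SCAMP5, PLD3, HLA-E and HLA-G passed both when any 1 array was left out and without the 3 arrays of 3'-biased RNA. JUNB and SLC2A1 passed without any 1 array but not without those 3 (adjusted p = 0.177 and 0.162). Of the genes that passed both, CYP2A6, CYP2A13 and SCAMP5 rest on r probe sets and HLA-G on an f probe set. Leaving out arrays does not test the specificity of a probe set. A single array ended the call of KIF2C (transplant SCC 3, 0.0626), HSP90AA1 and RPS6 (transplant SCC 1, 0.0506 and 0.0613) and RPL38 (transplant SCC 4, 0.0597). The call of CTSL was lost without immunocompetent SCC 8 or transplant SCC 1 (up to 0.0754), of RPS6KB2 without transplant SCC 3 or 4 (up to 0.0659), of EIF2S3 without transplant SCC 2, 3 or 4 (up to 0.0678), and of COL7A1 without immunocompetent SCC 2 or 5 or transplant SCC 4 (up to 0.108). CCNA2 lost it without immunocompetent SCC 5, 7 or 8 or transplant SCC 1, 2 or 4 (up to 0.102), KRT14 without immunocompetent SCC 7 or 8 or transplant SCC 1, 2, 3 or 4 (up to 0.0628), NDRG1 without immunocompetent SCC 3, 5, 7 or 8 or transplant SCC 1, 2, 3 or 4 (up to 0.124), and GUSBP11 without immunocompetent SCC 2, 5 or 6 or any transplant array (up to 0.121). EPHB3 lost it without normal skin 1, 2, 7 or 9, immunocompetent SCC 2, 3, 4, 6, 7 or 8 or transplant SCC 2, 3 or 4 (up to 0.132), and KLK7 without normal skin 2, 4, 7 or 9, any immunocompetent array but 5, or any transplant array but 2 (up to 0.105). UPP1 passed only when the array left out was normal skin 6 or immunocompetent SCC 1, 4 or 6 (up to 0.152 without another). With quantile normalization KRT14 (0.288) and KLK7 (0.0522) did not pass. Without the 3 arrays the 24 genes had a median share of 1.01 of their difference, but SLC2A1 went from 0.91 to 0.49, EPHB3 from -2.17 to -1.24, COL7A1 from -1.03 to -0.61, JUNB from -1.10 to -0.75 and KIF2C from 0.82 to 0.57. EIF2S3 (-2.80, adjusted p = 0.131) and RPS6KB2 (-1.85, 0.204) then did not pass either. With the GAPDH covariate EIF2S3 went to -2.08 (0.228), RPS6KB2 to -1.55 (0.197), EPHB3 to -0.98 (0.386), COL7A1 to -0.47 (0.322) and SLC2A1 to 0.50 (0.134).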

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

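The tests of spike-ins, of probe set suffixes, of a common dilution and of basal against cornified genes, and the exclusion of arrays with 3'-biased RNA, were chosen only after the results were seen.

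Between transplant and immunocompetent SCC 500 genes passed, while transplant SCC 3 and 4 held the most 3'-biased RNA and transplant SCC 1 the least by the GAPDH sign. Among 100 splits of these 13 arrays, only the real one gave as many (1 of 100, highest other 24), which argues against a chance split. Not all splits were drawn, and they treat the arrays as separate patients, which the labels do not state. Whether degraded RNA in transplant SCC 3 and 4 was the whole cause cannot be decided from the called genes. Without these arrays the median gene kept 0.936 of its difference (quartiles 0.817 and 1.04), 500 of 500 kept their direction and 0 fell under 0.25. But a gene shifted in those arrays alone would widen its own spread and could hardly be called. The choice of genes thus nearly fixed this result. Degradation as a part stays open: within normal and immunocompetent arrays, the slope on the GAPDH difference had the sign of the transplant difference in 58.4% of the 500 genes, and 17 of 100 rotations gave as much. That lies inside the bound set beforehand for rejecting it (35.0 to 64.6%), but the criterion was changed after the result was seen, since so wide a band would also hold an excess from a minority of genes and those arrays reach only 2.70 against 6.34 in transplant SCC 4; the immune status of the patients stays open too, untested.

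There were 59 probe sets higher in all 5 transplant arrays than in all 18 others and 17 lower, where chance gives 0.176 per direction (0.00297% of 5910). Probe sets of relaxed or shared design may account for a part: 32.2% of the 59 carried the suffixes r, i, f or s, against 12.7% of all kept probe sets (Fisher's exact test, two-sided, p = 7.04e-05). The excess lay in r, i or f, with 25.4% against 4.37% (Fisher's exact test, two-sided, p = 1.89e-08), and not in s. Of the 15 with suffix r, i or f, 8 genes had other kept probe sets that were not separated, and 2 of these 15 others were higher at adjusted p under 0.05 (limma); MAP2 gave 3.19 with its r probe set, 1.06 with its s probe set (adjusted p = 0.0489) and -0.19 with its i probe set, and PEX5 2.38 and -0.50. A different hybridisation batch cannot be told apart from immune status, because the labels give no batch and the spike-ins differed by 0.06 with an interval of -0.74 to 0.87 (exact permutation p = 0.872), too wide to exclude one. The probe sets of ordinary design among the 59 and a biological difference stay open.

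In both tumour groups the lists of fat, sweat gland, muscle, fibroblast and vessel markers passed camera as lower than in normal skin. The cornified envelope list passed as higher. With an estimated correlation, only sweat glands in transplant SCC kept a call (adjusted p = 0.0408). In transplant SCC 7 of 15 fibroblast genes fell, and of 16 cornified envelope genes 8 rose and 1 fell. The vessel call there was lost without the 3 arrays of 3'-biased RNA (camera adjusted p = 0.0629). One common dilution of all non-epidermal tissue would lower the marker lists by like amounts. Their medians were -4.41 for adipocytes, -3.76 for sweat glands, -3.31 for muscle, -1.49 for endothelium and -1.41 for fibroblasts in immunocompetent SCC (permutation of genes among lists, p = 0.0383). They ran from -4.70 to -1.16 in transplant SCC (p = 0.0392), with the largest falls bounded by the floor. These p-values treat genes as replicates and carry no spread between arrays. They cannot settle whether a common dilution is the whole cause. By permutation of genes, the basal median lay below the cornified one (0.00 against 0.96, p = 0.0189, and -0.19 against 0.83, p = 0.0052). It also did among genes with no array above 14 (p = 6.00e-04 and 9.00e-04). These p-values too treat genes as replicates. Over arrays, the basal list value was lower and the cornified one higher (exact permutation test, adjusted p = 0.00815 and 1.10e-04, and 0.0107 and 6.90e-04 in transplant SCC). In immunocompetent SCC 0 of 11 basal genes rose and 3 fell (CD151, COL7A1 and KRT15). In transplant SCC 2 rose, KRT14 and KRT5, and 4 fell. The basal list did not pass camera in either (adjusted p = 0.423 and 0.522). Loss of other tissue that also expresses basal genes was not tested. For these lists, a larger share of all keratinocytes alike is argued against as the whole cause but not excluded. Other changes in their share were not tested. A loss of fat and glands from the part of skin sampled, together with a change of the tumour cells, may remain, and the tumour itself as the biological difference was not separable from the tissue sampled.

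Splits of the arrays, with the same limits, argued against chance for the comparisons with normal skin as well: the real split was the 1 of 100 with as many genes for immunocompetent SCC (2398, highest other 658) and the 1 of 100 for transplant SCC (2336, highest other 1082).

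Of 407 sets of 5, 8 or 10 arrays, 35 held an array far from the others, where chance gives about 1 in 20, or 20.35. In normal skin 6 the ACTB 3' minus 5' difference was 4.95 (others 1.49 to 3.32), the spike-in mean 13.8 (8.75 to 10.5), the Notch list value -0.0412 (0.17 to 0.39), the ribosomal list value -0.0629 (0.12 to 0.25), and the levels of MMP1 3.88 (2.22 to 2.22) and SCAMP5 3.13 (3.64 to 3.81). Normal skin 1 was low in the neutrophil list value at -0.99 (others -0.58 to -0.20) and in IVL at 7.41 (8.66 to 9.75), JUNB at 6.74 (7.57 to 8.17) and TGM1 at 4.63 (5.68 to 6.67). Among the other normal arrays, normal skin 7 had CCL20 at 3.84 (2.40 to 3.05), normal skin 5 SOX10 at 5.43 (4.22 to 4.78) and normal skin 8 TTK at 3.30 (2.29 to 2.80).

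In immunocompetent SCC 4 the JAK-STAT list value was -0.50 (others -0.02 to 0.21), STAT5B was 4.58 (5.20 to 5.58) and HLA-F 7.32 (9.75 to 10.9). Immunocompetent SCC 5 had SCGB2A2 at 5.57 (2.50 to 3.16), immunocompetent SCC 1 TPI1 at 11.3 (10.4 to 10.7) and immunocompetent SCC 7 LGR5 at 8.63 (2.23 to 4.73).

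Transplant SCC 4, the array of most 3'-biased RNA, had an immediate-early list value of -0.37 (others 0.35 to 0.63), MYH11 at 5.82 (2.66 to 3.52), COL7A1 at 5.85 (7.65 to 7.87), S100A4 at 9.88 (8.98 to 9.21) and RPLP1 at 14.1 (14.4 to 14.5). In transplant SCC 5 the median of all probe sets was 3.83 (others 3.77 to 3.79), SPRR1B 13.8 (14.2 to 14.3), FASN 11.2 (8.03 to 8.63) and OASL 3.89 (6.77 to 7.89). Transplant SCC 1 had a Notch list value of -0.52 (others -0.25 to -0.15), a sweat gland list value of -1.60 (-2.06 to -2.01) and UPP1 at 10.7 (8.05 to 8.70). Transplant SCC 2 had CTSG at 4.30 (6.06 to 6.66), FCGR3B at 4.80 (2.33 to 2.42) and GUSBP11 at 2.94 (5.30 to 5.48), and transplant SCC 3 a T cell list value of 2.02 (others -0.43 to 0.27).

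Changes from normal skin ran in opposite directions, each past the threshold, in 8 genes, and the direct test of the difference gave, for transplant minus immunocompetent SCC, 0.89 for ABCC10, 1.30 for ALDH7A1, -0.95 for HLA-G, -1.31 for LARP1, -1.48 for PSMD3, -0.85 for RXYLT1, -1.08 for TLE4 and 0.66 for TLK2 (limma adjusted p from 0.00264 to 0.00747), small p-values that the choice of genes with opposite calls fixes. Among 687 kept probe sets with no symbol or several, which the comparisons left out, 327 passed for immunocompetent SCC against normal skin, 320 for transplant SCC against normal skin and 105 between the tumour groups.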

How the results depend on the processing

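Leaving out the arrays of 3'-biased RNA, the GAPDH covariate and leaving out single arrays from the tests of RNA quality were chosen only after the data were seen; all other alternatives were fixed before. Calls of at least 2-fold numbered 995 for immunocompetent SCC against normal skin, 1120 for transplant SCC against normal skin and 135 between the tumour groups, by the construction of that threshold, and 737 were shared by both comparisons with normal skin. The numbers of genes under other filters, probe set choices, variance models, array weights, scalings and fits of 2 groups stayed within 1.5 times those reported, except the number lower between the tumour groups in a fit of 2 groups (151 against 233; 354 genes in all). Leaving out 1 array gave 2248 to 2447, 2027 to 2377 and 333 to 589 genes in that order, 333 without transplant SCC 4 and 589 without normal skin 6. Between the tumour groups a rank sum test gave 190 genes (149 shared with the 500), leaving out the 3 arrays of 3'-biased RNA 189 (174 shared) and the covariate 202 (179 shared); the first pools no spread between genes, the second has fewer arrays, and the cause was not tested further. Of the named genes that passed, 59 of 61, 57 of 63 and 9 of 24 in the order of the comparisons passed without any 1 array, 61, 58 and 7 without the 3 arrays, 61, 59 and 9 with the covariate, and 60, 60 and 22 with quantile normalization.

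With the replicate number as a block, 1394 genes passed for transplant SCC against normal skin and 6 between the tumour groups, both from fewer arrays and fewer degrees of freedom. The labels do not say whether the numbers pair the samples. Arrays of the same number correlated from -0.23 to 0.18 (1 of 8 pairs over 0.1), -0.21 to 0.03 (0 of 5) and -0.19 to 0.13 (2 of 5) in the 3 comparisons. Only 1, 0 and 0 arrays correlated best with their own number. So few pairs gave no sign of pairing but cannot exclude it. The block ended 0 list calls and added 2 for transplant SCC against normal skin, hair follicle and sebaceous gland (0.0498) and IL-17 (0.00961).

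With an estimated correlation, 0 lists passed for immunocompetent SCC and 2 for transplant SCC against normal skin. Proliferation then had adjusted p = 0.305 and 0.263, and the feedback targets 0.262 in immunocompetent SCC, because the estimate widens the test. The tests of fry, which compare no list with other genes, called 21 lists (directional) and 20 (mixed) for transplant SCC against normal skin and 1 (mixed) between the tumour groups. Its mixed test passed JAK-STAT (2.98e-05) and calcineurin-NFAT (6.30e-06) in immunocompetent SCC. In transplant SCC the directional and mixed tests passed JAK-STAT (0.0311 and 5.83e-04), feedback targets (0.0113 and 4.36e-07) and calcineurin-NFAT (0.00173 and 5.91e-06). Leaving out 1 array gave 0 to 1 lists between the tumour groups, and 0.0203 to 0.499 for proliferation there. With the stricter filter, lists left with fewer than 3 genes gave no value.

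The overlap of both comparisons with normal skin was 1065 and 1099 with the normal arrays split, from fewer arrays. Among named genes and list values per array, directions turned in 4 that had passed. One was the calcineurin-NFAT list value of immunocompetent SCC with a median over genes (0.0257), whose mean took its sign from RCAN2. The others were another probe set of FBLN1 (0.0404, immunocompetent SCC), ADAM17 (-0.0363) and RPLP1 (0.12, both transplant SCC against normal skin). Why these probe sets differ was not tested. Directions also turned in 8 that had not passed, JAK1 in all 3 comparisons, STAT3 between the tumour groups and 4 list values per array. List medians of basal genes (immunocompetent SCC) and calcineurin-NFAT (transplant SCC) turned with scaling as reported. Leaving out 1 array turned 1 sign of RNA quality, the spike-in mean between the tumour groups (-0.126 to 0.304). About 40.0% of values lie near the floor, which limits what can be said of dim genes such as JAK3.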

Other observations

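The genes in this part were chosen after their values were seen, and no test of an explanation was run on them. Among the 59 probe sets higher in all 5 transplant arrays than in all other arrays, those without a suffix for relaxed design came from several kinds of gene. PTTG1 (securin, a regulator of chromosome separation) was higher in transplant than in immunocompetent SCC by 1.11 (limma adjusted p = 0.00414), and TK1, a thymidine kinase of S phase, by 1.03 (0.00447). PGAM1, a glycolytic enzyme, was higher by 0.65 (0.00264). A probe set of VEGFA, the vascular growth factor, had a mean of 9.30 ± 0.10 in transplant SCC (SD, n = 5) against 8.15 ± 0.48 in the other arrays, normal skin included (SD, n = 18). In the comparison of the tumour groups, with 1 probe set per gene, VEGFA was not among the 3 hypoxia genes that passed. The tRNA synthetases YARS1 and NARS1 were higher by 0.71 (0.00237) and 0.58 (0.00977), and KARS1 differed by 0.36 (0.101), which did not pass. A second probe set of STAT5B was also among the 59, with a mean of 6.11 ± 0.42 in transplant SCC (SD, n = 5) against 4.67 ± 0.37 elsewhere (SD, n = 18), while the STAT5B probe set used in the comparisons differed by 0.43 between the tumour groups and did not pass.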
